A study of Glycine max with 12 samples.

How the data were processed

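The study measured transcript levels in immature cotyledon explants of soybean (Glycine max) with the Affymetrix Soybean Genome Array. Explants came from embryos of 4-5 mm taken from greenhouse plants. They carried the 35S:GmAGL15 transgene or were non-transgenic (cultivar Jack). They were frozen at once (day 0) or after 3 or 7 days on D40 medium, which contains the synthetic auxin 2,4-D. Each of the 6 groups had 2 arrays, 12 in all. Per the labels, total RNA was purified on Qiagen RNeasy plant columns with an extraction buffer that contained PEG, and biotin-labelled cRNA was made by the Affymetrix procedure. The time given in a characteristics tag of 35S day 7 replicate 1 is 6 d, while its title, description and source say 7 days, and it was treated as day 7.

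The deposited values are array intensity per probe set on a linear scale. In every array the mean over all 61170 probe sets, the lowest and highest 2% left out, was 500, so the deposited values had been scaled array by array. The software behind them is not given in the sources used here. The table holds 37593 soybean probe sets, 23394 probe sets for the soybean pathogens Phytophthora sojae and Heterodera glycines, and 183 control and rRNA probe sets. Only soybean probe sets were tested. Their medians lay between 243 and 300.5 over the arrays, a ratio of 1.23, which is under the limit of 1.5 set for further normalization, so none was applied. Values were transformed to log2 after 16 was added.

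The 95th percentile of the probe sets for other organisms on each array was taken as background. It lay between 25.0 and 31.7. Between 77.4% and 83.0% of the soybean probe sets lay above it on an array, and 3444 lay at or below it on all 12 arrays. Where both arrays of a group were at or below background, a fold is given as a lower bound against that level. The number of arrays limits the precision of each value.

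A limma model (limma 3.58.1 in R 4.3.3) with 6 group means was fitted to all 12 arrays, with lmFit, contrasts.fit and eBayes. It had 6 residual degrees of freedom and 2.84 prior degrees of freedom. There were 13 contrasts: 35S minus Jack at each day and averaged over the days, the 3 differences of the genotype effect between days, and the 3 comparisons of days within each genotype. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the soybean probe sets of a contrast, with two-sided tests. Each log2 change is given ± its standard error from limma. These tests, the thresholds, the contrasts and the rule for naming genes were set before the data were examined. The replicate numbers were not used as a block, because the labels do not say what arrays of one number share. The labels do not say whether replicates came from separate plants, so the p-values measure only the spread between these samples.

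The platform's annotation table lists a gene for 9047 of the soybean probe sets and exactly 1 gene for 8677, which cover 6031 genes. It lists several genes for 370 and none for 28546. The gene ids of 8652 probe sets were found in a reference gene table of the assembly Glycine_max_v4.0, which changed 0 symbols. No build is named for the array, so no coordinates are given. The tables hold symbols and synonyms but no gene descriptions, and what a gene encodes is stated from general knowledge of the symbol. A gene identified only by a LOC number is given with its synonym in parentheses. No probe set is listed for AGL15 or AGL18, so the level of GmAGL15 itself was not analysed here.

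For each genotype contrast the rule named up to 10 genes with the highest positive and up to 10 with the largest negative change (5 of each for the averaged contrast, 3 of each for the others). They had to pass, to have exactly 1 listed gene, and to have arrays of the compared groups that did not overlap (for the averaged contrast, the same sign at all 3 days). A gene described as uncharacterized was to be left out. With no descriptions at hand this was applied as a symbol other than a LOC number, or a LOC number with a synonym. For such genes the probe set with the largest change was used. If none passed, the 5 with the smallest p were named as not passing. Members of the list of embryogenesis regulators were always named, of which LEC1-A and SERK1 had a probe set.

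Gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, using for each gene the probe set with the highest mean over the 12 arrays. Adjustment was over the lists of a contrast. Before the data were examined, 29 lists had been written as search terms for symbols and descriptions. With symbols only, 9 of them held 5 or more genes and 7 held none. A further 22 lists were written from the symbols after the annotation had been seen and before any comparison was computed. The 31 lists with 5 or more genes were tested, and some share genes. With the estimated correlation 0 list calls held in any contrast, so each camera call rests on the preset correlation. For lists fixed before the data were examined, the count of genes with p adjusted over the list alone is given too.

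The code was run on 37593 simulated probe sets, 50 changed per size, with equal spread in all groups. For 35S versus Jack at day 0 it recovered 22% of log2 changes of 1 and 66% of changes of 2. The shares were 32% and 68% at day 3, 40% and 78% at day 7 and 72% and 98% averaged. For the genotype difference at day 3 against day 0 they were 8% and 64%. Shares that use the more spread 35S day 0 arrays can thus be too high. False calls numbered 2 to 6 per comparison. No change was called in the wrong direction.

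Alternatives tried were centring each array on its soybean median, quantile normalization, adding 1 or 64 before the log2, leaving out probe sets at or below background, leaving out probe sets with _s_at or _x_at names, 1 probe set per gene, all probe sets of a list's genes, testing all probe sets of the table, a variance trend with robust moderation, array weights, a block for the replicate number, fitting only the compared arrays, other thresholds, and leaving out each array in turn. Leaving out 35S day 0 replicate 1 and Jack day 3 replicate 2 together was added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.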

Results

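Transcript levels were measured on 12 arrays hybridised with RNA from soybean cotyledon explants, with 2 arrays in each of 6 groups. The explants were 35S:GmAGL15 tissue, in which the cauliflower mosaic virus 35S promoter drives the soybean MADS-domain transcription factor GmAGL15, and non-transgenic Jack tissue. Each genotype was sampled at explant preparation (day 0) and after 3 and 7 days on a medium with 2,4-D, a synthetic auxin used to induce somatic embryos. The intensity at the median soybean probe set lay between 243 and 300.5, and background, from probe sets for other organisms, between 25.0 and 31.7. The study asked how the transcriptomes of the genotypes differ at explant preparation and during the first days of induction. The level of GmAGL15 itself was not analysed here, because no probe set is listed for it.

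Day of culture separated the arrays more than genotype did. The first principal component held 78.2% of the variance over 24098 probe sets and set the day 0 arrays apart from the cultured ones, and the next component held 8.99%. Replicates of a group correlated across probe sets at r from 0.983 to 0.992, except the day 0 arrays of 35S, at 0.962. Probe sets are not independent replicates. Between the 35S day 0 arrays 10.3% of probe sets differed more than 2-fold, against 1.35% to 3.72% between the other replicates, the highest of these for Jack day 3. On the first component 35S day 0 replicate 1 lay at -122, nearer to the cultured arrays than the other day 0 arrays, which lay between -174 and -186.

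**Figure D1:**
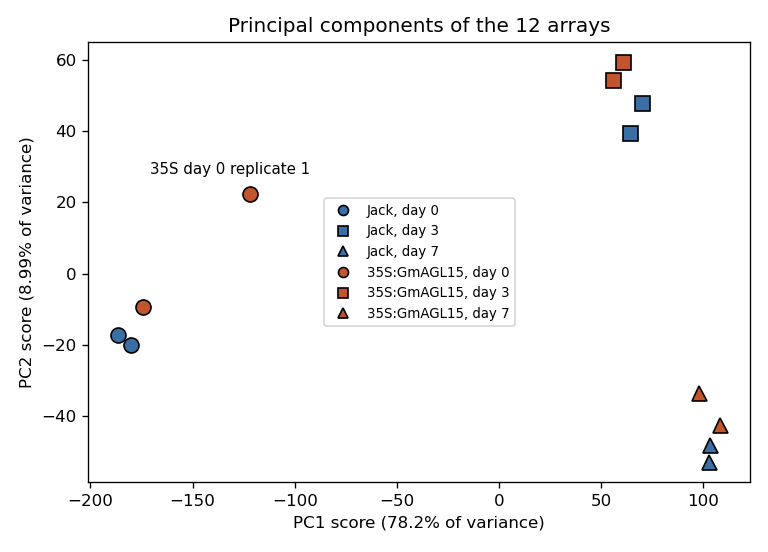
The 12 arrays on the first (horizontal, 78.2% of variance) and the next (vertical, 8.99% of variance) principal component of log2 intensity, with genotype shown by colour and day by marker shape. The day 0 arrays lie apart from the cultured arrays along the horizontal axis, and 35S day 0 replicate 1 lies nearest to the cultured ones.

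At explant preparation, the comparison asked whether transgenic cotyledons already differed before contact with the medium. The standard errors and p-values rest on 1 spread per probe set, shared by all 6 groups. The difference between replicates had a standard deviation of 0.709 for 35S day 0, against 0.328 to 0.471 for the other groups. The errors at day 0 can thus be too small, and 0 of the 20 named genes passed when only the day 0 arrays were fitted. The genes named as higher in 35S included genes of defence and stress (n = 2 arrays per genotype). PR10, a pathogenesis-related protein gene, was at least 28.1-fold higher in 35S (adjusted p = 0.0458), and lay at or below background in Jack. PRP2, encoding a proline-rich cell wall protein, was higher by 4.04 ± 0.78 on the log2 scale (adjusted p = 0.0326). Allene oxide synthase, an early enzyme of jasmonate synthesis, was higher by 3.73 ± 0.583 for AOS1 (adjusted p = 0.0178). The defence-associated transcription factors WRKY46 and WRKY5 were higher by 3.33 ± 0.412 and 3.25 ± 0.433 (adjusted p = 0.0097 and 0.0121). WRKY27 (3.63), the glutathione transferase genes GSTU58 (3.80) and GSTU13 (3.68), B13-1-1 (3.24) and DREB1, at least 9.55-fold higher, completed the 10 named rises. VSPA, a vegetative storage protein gene that jasmonate induces in leaves, was lower by -3.26 ± 0.456 at its probe set with the largest change (adjusted p = 0.0131). The VSPA probe set with the highest mean over the arrays, used for the lists, did not pass at day 0. The small heat shock protein gene HSP23.9 was lower by -2.97 ± 0.404 and the heat shock factor HSF-03 by -2.27 ± 0.326 (adjusted p = 0.0122 and 0.014). The other named falls were CYP83D1, at least 3.04-fold lower, HSP90A1 (-2.03), the lipoxygenase LOX7 (-2.00), MYB149 (-1.98), the clock factor LCL3 (-1.75), the seed coat protein gene SCB1 (-1.65) and the aquaporin SIP1-6 (-1.64).

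Among the regulators of embryogenesis, LEC1-A, an embryo-specific transcription factor gene, and the receptor kinase gene SERK1 did not pass at day 0. LEC1-A differed by -0.19 ± 0.204 (adjusted p = 0.652) and SERK1 by -0.08 ± 0.127 (adjusted p = 0.774).

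The WRKY and NAC lists of transcription factors shifted toward 35S at day 0, and the MYB (camera adjusted p = 0.365) and bZIP (0.708) lists were not called. Of 53 WRKY genes 9 were higher, 0 lower and 44 did not pass. Adjusted over the list alone, 19 were higher and 1 lower. The list had a median log2 difference of 0.373 and was called by camera (adjusted p = 1.87e-07; adjusted p = 0.29 with an estimated correlation). WRKY12 (2.39) was called beside those named above. Of 20 NAC genes 4 were higher and 0 lower, and adjusted over the list alone 10 were higher and 1 lower. The NAC median was 0.511 (camera adjusted p = 3.08e-05; adjusted p = 0.39 with an estimated correlation), with LOC100170751 (NAC32, 2.03), NAC27 (1.67), LOC100814504 (NAC69, 1.65) and NAC018 (1.45) called. Among glutathione transferases, enzymes of detoxification, and glucosyltransferases, 4 of 38 genes were higher and 0 lower, including GSTU30 (2.24) and GSTIR (0.95). Adjusted over the list alone 11 were higher and 2 lower. The median was 0.494 (camera adjusted p = 0.000113; adjusted p = 0.37 with an estimated correlation). The list of 21 defence genes had 2 higher and 0 lower, one of them PAD4 (1.96), with a median of 0.478 (camera adjusted p = 0.00161; adjusted p = 0.29 with an estimated correlation). The WRKY, NAC and glutathione transferase lists were fixed before the data were examined, and the defence list was written from the annotation's symbols.

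The lipoxygenase and photosynthesis lists were called toward Jack at day 0. All 10 genes of the jasmonate and lipoxygenase list are lipoxygenases, of which LOX7, VLXB (-1.46) and LOC547835 (LOX1.4, -1.43) were lower, 0 higher and 7 did not pass. Adjusted over the list alone 4 were lower. The median was -0.625 (camera adjusted p = 0.0449; adjusted p = 0.39 with an estimated correlation). Of 15 photosynthesis and chlorophyll genes 2 were lower, ATPC (-1.20) and CHLH (-1.20), and 0 higher, with a median of -0.361 (camera adjusted p = 0.00313; adjusted p = 0.29 with an estimated correlation). Further seed and secondary metabolism lists were called toward 35S with 0 single genes passing. The list of 29 late embryogenesis abundant protein genes, whose search terms also matched PARP3 and TENA_E, had a median of 0.486 (camera adjusted p = 0.00902; adjusted p = 0.755 with an estimated correlation), with 0 called adjusted over the list alone. The 31 seed maturation genes, an overlapping list, had a median of 0.634 (camera adjusted p = 0.00597; adjusted p = 0.755 with an estimated correlation). The 36 phenylpropanoid and isoflavonoid genes had a median of 0.363 (camera adjusted p = 0.0235; adjusted p = 0.755 with an estimated correlation). The seed storage protein list and the list of 25 storage protein and protease inhibitor genes were not called (camera adjusted p = 0.604 and 0.721), with 0 genes passing in either. Of 14 jasmonate and vegetative storage genes 4 were higher, all in jasmonate synthesis, AOS1, AOS2 (3.08), AOC6 (3.01) and AOC4 (2.20), and 2 lower, and the list was not called (camera adjusted p = 0.544). Of 13 ERF and DREB genes, DREB1 and LOC732579 (DREB2, 2.51) were higher, 3 when adjusted over the list alone (camera adjusted p = 0.206). Of 9 ethylene genes 2 were higher, both for ACC synthase, ACS1 (2.68) and ACS (1.33), and the list was not called (camera adjusted p = 0.0555). Of 6 heat shock protein genes 3 were lower, HSP23.9, HSP90A1 and HSP90-1 (-0.62), the same count adjusted over the list alone (camera adjusted p = 0.0555). In every list result, the calls rest on the preset correlation. The fry test asks whether the genes of a list shifted together in a shared direction, without comparing them with other genes. By fry the WRKY, glutathione transferase, defence, lipoxygenase and photosynthesis lists were called at day 0 as well. The NAC (adjusted p = 0.0559), late embryogenesis (0.473), seed maturation (0.462) and phenylpropanoid (0.38) lists were not called by fry, and the ERF and DREB (0.0183), heat shock protein (0.0201) and ethylene (0.0105) lists were called by fry alone.

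At day 0, 1307 probe sets passed, 665 higher and 642 lower in 35S, and 399 of them had 1 listed gene. As a measure of RNA quality, the log2 ratio of 3′ to 5′ actin control probe sets was 2.07 and 2.09 in Jack and 2.02 and 2.03 in 35S, and that of 3′ to middle GAPDH probe sets overlapped (0.679 and 0.790 against 0.694 and 0.779). The count depended on single arrays. It was 78 without Jack day 0 replicate 2, 667 without Jack day 0 replicate 1, 672 without 35S day 0 replicate 1 and 6137 without 35S day 0 replicate 2. It was 576 without either Jack day 7 array, 559 without either 35S day 3 array and 642 without either 35S day 7 array. All 20 named genes kept their sign without any 1 array, which the naming rule fixed in advance by asking for arrays that did not overlap. Of them 2 passed without Jack day 0 replicate 2, 9 without Jack day 0 replicate 1, 15 without 35S day 0 replicate 1, 19 without 35S day 0 replicate 2 and 10 or 12 without 1 of the cultured arrays. Without 35S day 0 replicate 1 all 10 rises were smaller, at 2.43 for PRP2, 2.58 for AOS1, 2.60 for WRKY46, 2.53 for WRKY5, 2.38 for WRKY27, 2.28 for GSTU58, 2.26 for GSTU13 and 2.18 for B13-1-1. The fitted rises of PR10 and DREB1, which a bound replaces above, were 2.65 and 1.78 instead of 4.85 and 3.25. Of the falls, HSP23.9 (-3.63), HSF-03 (-2.74), HSP90A1 (-2.65), LOX7 (-2.16), LCL3 (-1.91) and SIP1-6 (-1.87) were larger without that array, and VSPA (-2.70), MYB149 (-1.51), SCB1 (-1.26) and CYP83D1 were smaller. In the list results, the WRKY, NAC, glutathione transferase and defence calls stood without any 1 array, but the glutathione transferase median was 0.11 without 35S day 0 replicate 1 and the NAC median 0.892 without 35S day 0 replicate 2. Without 35S day 0 replicate 1 the late embryogenesis (0.338), seed maturation (0.338) and phenylpropanoid (-0.0371) calls ended, and the phenylpropanoid call also ended without Jack day 0 replicate 1 (0.237) and without _s_at and _x_at probe sets (0.111). The photosynthesis call ended without 35S day 0 replicate 2 (-0.27). The lipoxygenase call ended without Jack day 0 replicate 2, either Jack day 3 array or either 35S day 0 array, with medians from -1.2 to -0.296 over the 12 arrays left out in turn. It also ended with 1 added before the log2 (-0.773), and, with the median at -0.625, under a variance trend with robust moderation, array weights, a replicate block and a fit to the compared arrays alone.

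**Figure D2:**
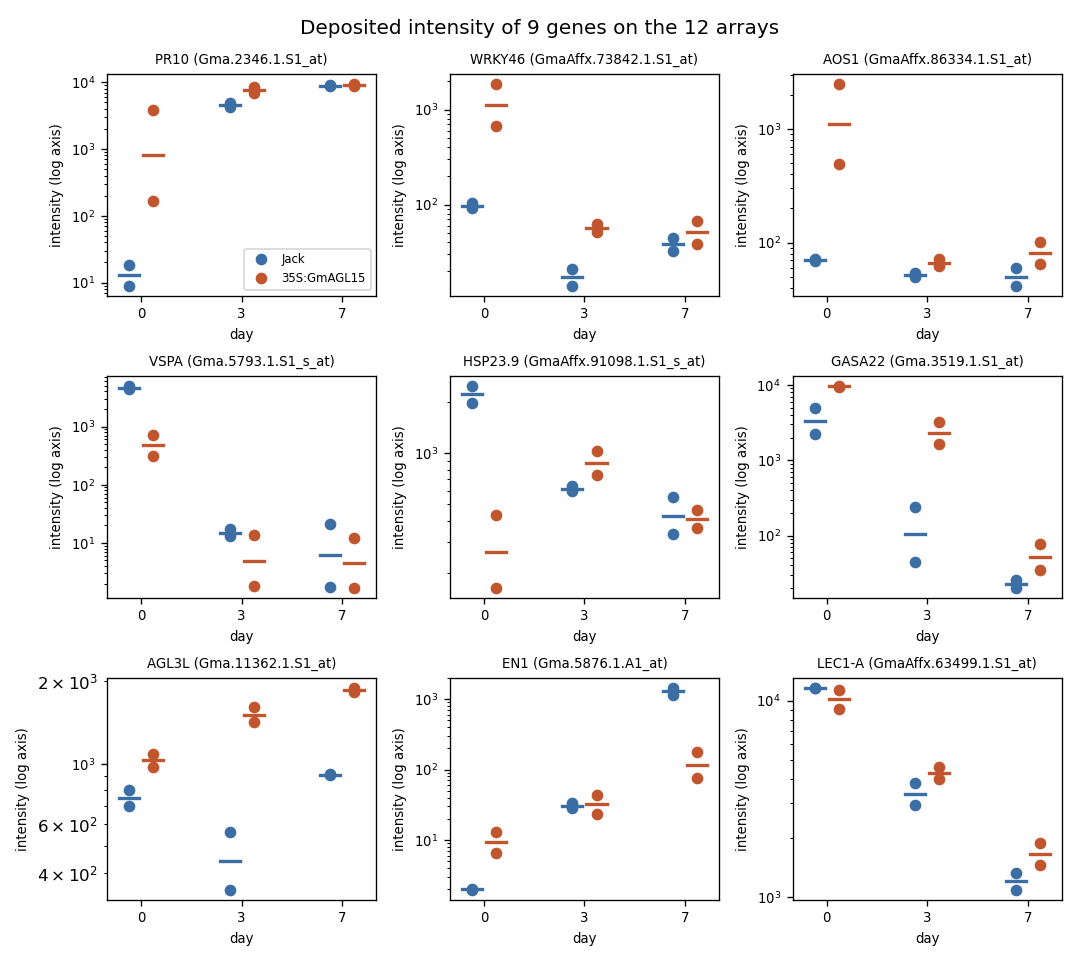
Intensity (log axis, array units) of 9 genes by day for Jack and 35S, with points for the 2 arrays of a group and bars for their geometric mean. PR10, WRKY46 and AOS1 are higher and VSPA and HSP23.9 lower in 35S at day 0, GASA22 and AGL3L are higher in 35S at day 3, and EN1 is lower in 35S at day 7. The VSPA probe set drawn is not the one with the gene's highest mean, which did not pass at day 0.

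After 3 days of culture on the medium with 2,4-D, the named gene with the largest genotype difference was GASA22, of a gibberellin-regulated peptide family. It was higher in 35S by 4.19 ± 0.654 (n = 2 arrays per genotype, adjusted p = 0.0413). The MADS-box gene AGL3L was higher by 1.74 ± 0.21 (adjusted p = 0.017), and CYP93E1, which acts in triterpenoid saponin synthesis, by 1.86 ± 0.25 (adjusted p = 0.0253). The glutathione transferase genes LOC547576 (GSTU3) and LOC100306119 (GSTU5) were higher by 1.68 ± 0.147 and 1.90 ± 0.315 (adjusted p = 0.00448 and 0.0464). RCAALPHA, encoding Rubisco activase, was higher by 1.66, LOC100806152 (TPR1) by 1.46, CYP71D10 by 1.35, the leaf-patterning factor PHANa by 1.28, and FBA by at least 1.07-fold. PR1-7, a pathogenesis-related gene, was lower by -1.95 ± 0.301 (adjusted p = 0.0401). LEC1-A (0.36 ± 0.204, adjusted p = 0.414) and SERK1 (-0.36 ± 0.127, adjusted p = 0.216) did not pass. In all, 191 probe sets passed, 147 higher and 44 lower in 35S. The log2 ratio of 3′ to 5′ actin probe sets was 2.70 and 2.95 in Jack and 2.60 and 2.69 in 35S, and that of 3′ to middle GAPDH probe sets 0.822 and 0.991 against 0.664 and 0.762. Both ratios were higher in Jack without overlap, although 33.3% of orderings of 2 arrays against 2 show no overlap by chance. A difference in RNA quality at day 3 can thus not be set apart from genotype.

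At day 3 the list of 25 seed storage protein and protease inhibitor genes was called toward 35S with 0 genes passing, 22 of 25 positive and a median of 1.18 (camera adjusted p = 0.0233; adjusted p = 0.893 with an estimated correlation). The call ended without Jack day 3 replicate 2, where the median was 0.351, and without 35S day 3 replicate 1 (1.02), and the median was 2.18 without Jack day 3 replicate 1. Photosynthesis genes were called toward 35S, with RCAALPHA higher, 14 of 15 not passing and a median of 0.345 (camera adjusted p = 0.0446; adjusted p = 0.893 with an estimated correlation). That call ended without Jack day 3 replicate 1 (0.313), either 35S day 0 array (0.345) or 35S day 3 replicate 1 (0.294), and without _s_at and _x_at probe sets (0.166). It ended also with a replicate block and with a variance trend and robust moderation, both at 0.345. By fry the photosynthesis list was called and the storage list was not (adjusted p = 0.465), and gibberellin genes were called by fry alone (adjusted p = 0.0348). Glutathione transferases had 3 of 38 genes higher, the last GSTU1 (1.23), and 5 adjusted over the list alone, without a camera call (adjusted p = 0.0822). None of the WRKY genes passed (0 of 53, by limma), and the list was not called (camera adjusted p = 0.871). The count of 191 probe sets at day 3 was 10 and 15 without 35S day 3 replicate 1 and replicate 2, 19 without Jack day 3 replicate 2 and 1336 without Jack day 3 replicate 1. It was 68 without either Jack day 0 array, 89 without either Jack day 7 array and 431 without either 35S day 0 array. All 11 named genes kept their sign, again fixed in advance by the naming rule. None of the 11 passed without either 35S day 3 array, 1 (LOC547576) without Jack day 3 replicate 2, 3 without either Jack day 0 array, and 5 without 1 of the day 7 arrays. GASA22 differed by 3.14 and AGL3L by 1.40 without Jack day 3 replicate 2. With a replicate block, which leaves the differences as they are, GASA22, LOC100306119, LOC100806152, PHANa, FBA and PR1-7 lost their calls. Median centring and quantile normalization each ended the calls of LOC100306119 and CYP71D10.

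After 7 days, 45 probe sets passed, 14 higher and 31 lower in 35S (n = 2 arrays per genotype). EN1 was lower by -3.30 ± 0.331 (adjusted p = 0.00849), and LOC100306092 (TIP2-3), an aquaporin gene of the vacuolar membrane, by -1.56 ± 0.207 (adjusted p = 0.0381). No gene that met the naming rule was higher. LEC1-A (0.45, adjusted p = 0.913) and SERK1 (-0.27, adjusted p = 0.934) did not pass. None of the 31 lists was called (0 by camera and 0 by fry), and the lowest adjusted p was 0.0555, for the cell wall list, with 12 of 12 genes negative and a median of -0.175. EN1 lost its call without either Jack day 7 array. LOC100306092 lost it without any 1 of the day 7 arrays, either Jack day 0 array or either 35S day 3 array. The count of 45 was 25 and 20 without Jack day 7 replicate 1 and replicate 2, 68 and 16 without 35S day 7 replicate 1 and replicate 2, and 29 without either 35S day 3 array.

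Averaged over the days (n = 6 arrays per genotype), 543 probe sets passed, 279 higher and 264 lower in 35S. A large difference at 1 day can raise this mean, as for GASA22 (4.19 at day 3) and WRKY46 (3.33 at day 0). GASA22 was higher by 2.18 ± 0.378 (adjusted p = 0.0355), WRKY46 by 1.59 ± 0.238 (adjusted p = 0.0238), WRKY5 by 1.39 ± 0.25 (adjusted p = 0.0386), the ethylene response factor ERF5 by 1.1 ± 0.213 (adjusted p = 0.048) and AGL3L by 1.07 ± 0.121 (adjusted p = 0.0107). LOC100306092 was lower by -0.93 ± 0.167 (adjusted p = 0.0389), the calmodulin-binding protein gene IQD45 by -0.70 ± 0.0907 (adjusted p = 0.017) and CYP93A2 by -0.50 ± 0.0896 (adjusted p = 0.0369). Each of these had the same sign at all 3 days, as the naming rule required. LEC1-A (0.21, adjusted p = 0.346) and SERK1 (-0.24, adjusted p = 0.126) did not pass. Among glutathione transferases GSTU30 (0.69) and LOC547576 (0.61) were higher, 7 adjusted over the list alone, and 31 of 38 were positive with a median of 0.292 (camera adjusted p = 0.000159; adjusted p = 0.723 with an estimated correlation). WRKY genes had 2 higher and 0 lower, 9 adjusted over the list alone, and a median of 0.242 (camera adjusted p = 0.00253; adjusted p = 0.723 with an estimated correlation). NAC genes had LOC100170751 (0.80) and NAC22 (0.48) higher, 5 adjusted over the list alone, and a median of 0.372 (camera adjusted p = 0.000571; adjusted p = 0.723 with an estimated correlation). Phenylpropanoid genes had 0 passing, 29 of 36 positive and a median of 0.265 (camera adjusted p = 0.00584; adjusted p = 0.775 with an estimated correlation). That last call ended without Jack day 0 replicate 1 (0.255) and without _s_at and _x_at probe sets (0.101). Without 35S day 0 replicate 1 the WRKY and phenylpropanoid calls stood with medians of 0.115 and 0.112. The WRKY median was 0.147 without Jack day 0 replicate 2, and the NAC median 0.241 without Jack day 3 replicate 2. With 35S day 0 replicate 1 and Jack day 3 replicate 2 both left out the NAC (0.188) and phenylpropanoid (0.0932) calls ended. By fry none of these 4 lists was called (adjusted p from 0.099 to 0.267), and the ERF and DREB (0.0154), ethylene (0.0154) and flowering (0.0187) lists were.

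The averaged count of 543 was 255 and 75 without Jack day 0 replicate 1 and replicate 2, 1689 and 88 without Jack day 3 replicate 1 and replicate 2, and 93 and 124 without Jack day 7 replicate 1 and replicate 2. It was 5334 without 35S day 0 replicate 2, 55 and 78 without 35S day 3 replicate 1 and replicate 2, and 262 and 53 without 35S day 7 replicate 1 and replicate 2. Without 35S day 0 replicate 1 it stayed within 1.5 times. Of the 8 named genes 0 passed without 35S day 3 replicate 1, and 1, AGL3L, without Jack day 0 replicate 2, either Jack day 7 array or 35S day 7 replicate 2. Only AGL3L and IQD45 passed without Jack day 0 replicate 1, Jack day 3 replicate 2 or 35S day 3 replicate 2. WRKY46, LOC100306092, AGL3L and IQD45 passed without 35S day 7 replicate 1, 6 without 35S day 0 replicate 1, 7 without Jack day 3 replicate 1 and 8 without 35S day 0 replicate 2. AGL3L passed in 23 of 24 settings. ERF5 passed without 35S day 0 replicate 2 and failed without any other 1 array. GASA22 passed without 35S day 0 replicate 2 or Jack day 3 replicate 1 and failed without any other 1 array. All 8 kept their sign.

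At all 3 days 14 probe sets passed in the same direction, 9 higher and 5 lower in 35S. Only 1 of them has a listed gene, LOC100789895, which was lower by -2.10, -2.13 and -1.35 at days 0, 3 and 7, and it is named because the count is small, after its values were seen. The other 13 have no listed gene and were likewise looked at after their values were seen. One of the higher probe sets had intensities from 22.6 to 43.8 in Jack and from 775 to 1249 in 35S (adjusted p = 7.55e-05 at day 0). One of the lower probe sets lay between 6762 and 10400 in Jack and between 41.6 and 75.8 in 35S, and was lower by -6.84 ± 0.194, -6.76 and -6.95 at days 0, 3 and 7 (adjusted p = 3.07e-06 at day 0). Days share no arrays, but they share 1 variance estimate per probe set, so no chance level is given for an overlap of calls. Days 0 and 3 shared 18 higher and 8 lower probe sets, with 3 called in opposite directions. Days 0 and 7 shared 9 and 9, with 0 in opposite directions, and days 3 and 7 shared 11 and 5, with 2. Across all soybean probe sets, which are not independent replicates, the genotype differences at days 0 and 3 correlated at r = 0.154, at days 0 and 7 at 0.152 and at days 3 and 7 at 0.349.

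Culture on 2,4-D medium itself was followed within each genotype. The log2 ratio of 3′ to 5′ actin control probe sets was 2.02 to 2.09 at day 0 and 2.40 to 2.95 in cultured arrays. The GAPDH ratio, of 3′ to middle probe sets, was 0.679 to 0.790 at day 0, 0.813 to 1.00 in cultured Jack arrays, 0.664 and 0.762 in 35S at day 3 and 0.805 and 0.916 in 35S at day 7. Both ratios were thus higher with culture in Jack and in 35S at day 7, and the actin ratio alone in 35S at day 3. This can reflect RNA quality, but the ratios alone do not show it. In Jack after 3 days (n = 2 arrays per day), genes of seed filling fell. The seed oleate desaturase gene FAD2-1A fell by 8.73 ± 0.59 (adjusted p = 6.94e-06), the glycinin gene GY2 was at least 284-fold lower (adjusted p = 9.91e-05) and VSPA at least 389-fold lower (adjusted p = 1.32e-06). The chitinase gene CHIA1 was at least 470-fold higher (adjusted p = 1.1e-07), the glutathione transferase gene GST3 at least 471-fold higher, and the gene with the symbol H4 at least 670-fold higher (adjusted p = 0.000386). LEC1-A fell by 1.80 ± 0.204 (adjusted p = 0.000141), and SERK1 (0.20, adjusted p = 0.238) did not pass. In all 16226 probe sets passed, 7912 higher and 8314 lower.

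Storage protein, Kunitz inhibitor, lipoxygenase, oil and photosynthesis lists fell in Jack by day 3. The 29 late embryogenesis abundant protein genes, with 4 up and 7 down, and the 31 seed maturation genes, with 3 up and 7 down, were not called (medians 0.00274 and 0.0246, camera adjusted p = 0.971 for both). Of 8 seed storage protein genes 6 fell and 0 rose, 7 adjusted over the list alone, among them GY5 (-5.82) and CG-1 (-3.91), with a median of -3.46 (camera adjusted p = 0.0167; adjusted p = 0.389 with an estimated correlation). That call ended with 35S day 0 replicate 1 and Jack day 3 replicate 2 both left out (-2.55). In a list of 4 Kunitz trypsin inhibitor genes with the thiol protease gene P34 and CYP34, which the search term for P34 also matched, 4 of 6 genes fell, KTI-3 (-7.90), KTI-2 (-7.61), P34 (-7.36) and KTI1 (-7.06), the same 4 adjusted over the list alone, with a median of -7.21 (camera adjusted p = 0.00512; adjusted p = 0.321 with an estimated correlation). In the joint list of 25 storage and inhibitor genes, which also holds P34 and 3 lipoxygenases, 16 fell and 1 rose (median -3.60, camera adjusted p = 0.00156; adjusted p = 0.519 with an estimated correlation), and the median was -2.34 without Jack day 3 replicate 2. Lipoxygenases fell in 9 of 10 genes, with LOX2 (-6.51) and VLXB (-4.35), and 9 adjusted over the list alone (median -3.52, camera adjusted p = 0.00395; adjusted p = 0.321 with an estimated correlation). Fatty acid and oil genes fell in 13 of 20 and rose in 1, with the desaturase SACPD-C (-6.94), the oil regulator WRI1B (-3.28) and the riser FAD3C (3.16) (median -0.747, camera adjusted p = 0.00377; adjusted p = 0.321 with an estimated correlation). Photosynthesis genes fell in 10 of 15 and rose in 2, with ATPC (-4.48), CAB3 (-3.92) and CHLH (-3.48) (median -1.21, camera adjusted p = 0.00228; adjusted p = 0.321 with an estimated correlation).

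Defence, detoxification and regulatory lists rose in Jack by day 3. Of 53 WRKY genes 25 rose and 4 fell, 27 and 4 adjusted over the list alone, with WRKY51 (7.06) and WRKY19, at least 47.9-fold higher (median 0.831, camera adjusted p = 0.00093; adjusted p = 0.321 with an estimated correlation). NAC genes rose in 12 of 20 and fell in 1, 13 and 1 adjusted over the list alone, with NAC27 (5.62), NAC4 (5.54) and NAC23 (4.35) (median 1.37, camera adjusted p = 0.00377; adjusted p = 0.449 with an estimated correlation). Glutathione transferases rose in 26 of 38 and fell in 5, 27 and 5 adjusted over the list alone, with GSTU42 at least 753-fold higher and LOC547578 (GSTU26) higher by 6.99 (median 1.59, camera adjusted p = 0.000427; adjusted p = 0.321 with an estimated correlation). Defence genes rose in 11 of 21 and fell in 2, with PR-10 at least 738-fold and the osmotin-like OLPa at least 222-fold higher (median 0.859, camera adjusted p = 0.00394; adjusted p = 0.321 with an estimated correlation). Phenylpropanoid genes rose in 18 of 36 and fell in 7, with the isoflavone reductase IFR at least 229-fold higher and CHS8 (7.46), a chalcone synthase (median 0.944, camera adjusted p = 0.0445; adjusted p = 0.745 with an estimated correlation). That call ended without Jack day 0 replicate 1, Jack day 3 replicate 1 or either 35S day 7 array, with medians from 0.756 to 1.13 over the arrays left out, and without _s_at and _x_at probe sets (0.057). MYB genes rose in 25 of 66 and fell in 7, with MYB184 at least 130-fold higher and MYB73 (5.46) (median 0.347, camera adjusted p = 0.0406; adjusted p = 0.321 with an estimated correlation), with a median of 0.226 without Jack day 3 replicate 2.

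By day 7 in Jack, CHIA1 was at least 515-fold higher than at day 0 (adjusted p = 6.46e-08), the cytochrome P450 gene CYP82A2 at least 452-fold (adjusted p = 0.000105) and GST3 at least 457-fold, while VSPA was at least 379-fold lower, GY2 at least 276-fold lower and FAD2-1A fell by 8.51 (n = 2 arrays per day). LEC1-A fell by 3.26 ± 0.204 (adjusted p = 2.91e-06), and SERK1 rose by 0.44 ± 0.127 (adjusted p = 0.0193). Centring arrays on their median moves every change in this comparison by -0.241, a large part of the SERK1 rise, which thus depends on the scaling. WRKY genes rose in 34 of 53 and fell in 3, 36 and 6 adjusted over the list alone, with WRKY19 at least 104-fold and WRKY53 at least 78.7-fold higher (median 1.61, camera adjusted p = 5.43e-05; adjusted p = 0.293 with an estimated correlation). NAC genes rose in 14 of 20 and fell in 1 (median 2.85, camera adjusted p = 0.000232; adjusted p = 0.387 with an estimated correlation), and defence genes rose in 13 of 21 and fell in 4, with PR1-7 at least 372-fold higher (median 3.73, camera adjusted p = 0.00214; adjusted p = 0.293 with an estimated correlation). The defence call ended without _s_at and _x_at probe sets, with a median of 0.801. In the list of Kunitz inhibitor genes with P34 and CYP34 6 of 6 genes fell, KTI1 at least 334-fold (median -7.83, camera adjusted p = 0.00307; adjusted p = 0.293 with an estimated correlation). Of 6 heat shock protein genes 4 fell (median -1.87, camera adjusted p = 0.0367; adjusted p = 0.293 with an estimated correlation), with HSP90A1 at -2.59 and HSP23.9 at -2.22, and that call ended without Jack day 0 replicate 1 (-1.63). As at day 3, 13 of 31 lists were called, 6 up and 7 down. In all 17326 probe sets passed, 8848 higher and 8478 lower, a balance that depended on the scaling.

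Between days 3 and 7 in Jack, 5406 probe sets passed, 3323 higher and 2083 lower, and which direction prevailed depended on the scaling. LOC100527788 (SPEAR6) was at least 106-fold and SLR1 at least 66.6-fold higher, and the nodulin gene NOD33 rose by 5.60 ± 0.297 (n = 2 arrays per day, adjusted p = 4.31e-05, 4.31e-05 and 2.81e-05). PSK1 fell by 2.48 ± 0.335 (adjusted p = 0.00207), IQD40 by 2.25 ± 0.304 (adjusted p = 0.002) and the transcription factor subunit NF-YA13 by 2.15 ± 0.27 (adjusted p = 0.00139). LEC1-A fell by a further 1.46 (adjusted p = 0.00242), and SERK1 (0.24, adjusted p = 0.253) did not pass. Cell wall genes were positive in 12 of 12, with 6 passing, among them the expansin CIM1 (4.81), the xyloglucan-modifying XET1, at least 7.25-fold higher, PRP1 (2.43) and PRP3 (2.24) (median 1.39, camera adjusted p = 9.95e-05; adjusted p = 0.0832 with an estimated correlation). NAC genes rose in 7 of 20, with NAC1 at least 13.8-fold higher, NAC26 (3.36) and NAC12 (3.00) (median 0.685, camera adjusted p = 0.0336; adjusted p = 0.69 with an estimated correlation), a call that ended without Jack day 3 replicate 2 (0.528) or Jack day 7 replicate 1 (0.708) and without _s_at and _x_at probe sets (0.537). The count of 5406 was 2709 without Jack day 3 replicate 2, and 2208 and 1663 without Jack day 7 replicate 1 and replicate 2.

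In 35S many of the same genes changed with culture (n = 2 arrays per day). By day 3, 13790 probe sets passed against day 0, 6939 higher and 6851 lower. INR2, for an inducible nitrate reductase, was at least 230-fold higher (adjusted p = 2.04e-07), CHIA1 at least 220-fold, and LOC100778056 (CYP82A4) rose by 8.09 ± 0.421, while GY2 fell by 7.72, FAD2-1A by 7.51 and SACPD-C by 6.94. By day 7, 15760 passed, 8170 higher and 7590 lower, with CHIA1 at least 502-fold, PR1-7 at least 343-fold and the Bowman-Birk inhibitor gene BBI-1 at least 374-fold higher, KTI1 at least 370-fold lower, and GY2 (-9.02) and FAD2-1A (-8.40) lower. LEC1-A fell by 1.24 by day 3 (adjusted p = 0.00143) and by 2.61 by day 7 (adjusted p = 1.27e-05), and SERK1 did not pass at either (adjusted p = 0.671 and 0.155). From day 3 to day 7, 3761 passed, 2309 higher and 1452 lower, with LOC100527788 at least 95.3-fold higher, PR1-7 (6.42) and NOD33 (6.15) higher, GASA22 (-5.05 ± 0.654, adjusted p = 0.00169) and GASA27 (-2.85 ± 0.555) lower, and SALI5-4A at least 3.46-fold lower. In 35S too, which direction prevailed by day 7, against day 0 or day 3, depended on the scaling. The count of 3761 was 1722 and 1765 without 35S day 3 replicate 1 and replicate 2, and 1670 and 2284 without 35S day 7 replicate 1 and replicate 2.

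The lists called in 35S overlapped those in Jack. By day 3, 23 of 38 glutathione transferases rose and 5 fell (median 1.20, camera adjusted p = 0.000751; adjusted p = 0.362 with an estimated correlation), 14 of 20 fatty acid and oil genes fell and 2 rose (median -1.27, camera adjusted p = 0.000751; adjusted p = 0.352 with an estimated correlation), and 29 of 66 MYB genes rose and 2 fell (median 0.456, camera adjusted p = 0.000751; adjusted p = 0.352 with an estimated correlation). Of 14 jasmonate and vegetative storage genes 9 fell and 2 rose, with AOC4 (-6.06), AOC6 (-5.19) and AOS1 (-3.78) (median -1.33, camera adjusted p = 0.0144; adjusted p = 0.352 with an estimated correlation). WRKY genes rose in 23 of 53 and fell in 8 in 35S by day 3, WRKY46 among the falls (-3.97), without a camera call (adjusted p = 0.0604). By day 7 the WRKY list was called, 26 up and 6 down (median 1.19, camera adjusted p = 0.0126; adjusted p = 0.472 with an estimated correlation), and all 8 storage protein genes had fallen (median -4.38, camera adjusted p = 0.00621; adjusted p = 0.472 with an estimated correlation). From day 3 to day 7 the cell wall list was positive in 12 of 12 genes, with 7 passing, XTH1 (2.95) and PRP1 (2.96) among them (median 1.59, camera adjusted p = 8.73e-05; adjusted p = 0.0808 with an estimated correlation). Without 35S day 0 replicate 1, 10 of the 13 lists called by day 3 stayed called. The calls that ended were those of lipoxygenases (-1.43), photosynthesis (-0.791) and aquaporins (-0.491). Without 35S day 3 replicate 2 the lipoxygenase (-1.15) and aquaporin (-0.74) calls ended too.

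Across all soybean probe sets, the changes in Jack and 35S, which share no arrays, correlated at r = 0.881 from day 0 to 3, 0.924 from day 0 to 7 and 0.795 from day 3 to 7. From day 0 to 3 both genotypes called 5210 probe sets higher and 5398 lower, while 66 were called in opposite directions. Between days 0 and 7 the shared counts were 6679 and 6217, with 48 in opposite directions. Centring arrays on their median moved the median log2 change between days 0 and 7 by -0.241 in Jack and -0.181 in 35S, and between days 3 and 7 by -0.179 and -0.109. Quantile normalization moved that between days 0 and 7 in Jack by -0.138. The share of passing probe sets that rose between days 0 and 7 in Jack was 51.1% as scaled by the authors and 36.9% after centring. None of the called lists changed the sign of its median under either scaling.

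**Figure D3:**
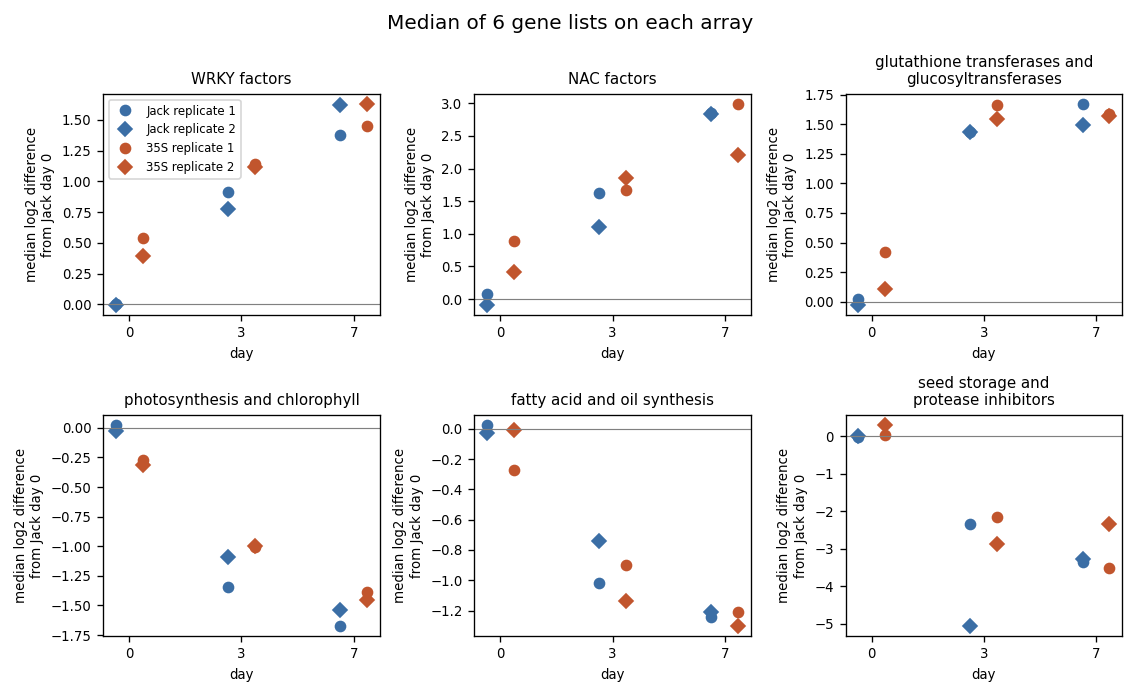
Median log2 difference from the Jack day 0 mean over the genes of 6 lists (vertical axis), by day, with 1 point per array and colour for genotype. WRKY, NAC and glutathione transferase medians are higher in 35S than in Jack at day 0 and rise with culture, and photosynthesis, fatty acid and storage medians fall.

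Whether the genotype difference changed with culture was tested directly. From day 0 to day 3 it changed for 276 probe sets, 214 toward 35S and 62 toward Jack (n = 2 arrays per group). HSF-03 (3.49 ± 0.461, adjusted p = 0.0312), HSP23.9 (3.46 ± 0.571, adjusted p = 0.0406) and VSPA (3.32 ± 0.558, adjusted p = 0.0406), lower in 35S at day 0, moved toward 35S. At day 3 this VSPA probe set, which is not the one with the gene's highest mean, lay at or below background in both genotypes. Its change is thus the loss of the day 0 difference. The jasmonate synthesis gene AOC4 (-2.66 ± 0.443, adjusted p = 0.0406), GSTU30 (-2.41 ± 0.295, adjusted p = 0.0252) and the glutamate dehydrogenase gene GDH1 (-1.98 ± 0.347, adjusted p = 0.0467) moved toward Jack. All 6 kept their sign without any 1 array, passed without either 35S day 0 array and failed without any 1 of 7 arrays, both of Jack day 0, Jack day 7 and 35S day 3 and Jack day 3 replicate 2. Quantile normalization and a replicate block each ended the calls of VSPA, AOC4 and GDH1, median centring that of GDH1, and array weights all 6. The count of 276 was 0 without Jack day 3 replicate 2 or either 35S day 3 array, 55 and 0 without Jack day 0 replicate 1 and replicate 2, 46 without either Jack day 7 array and 66 without either 35S day 7 array. It was 556 and 3523 without 35S day 0 replicate 1 and replicate 2. For day 7 against day 0 only 2 probe sets passed by limma (4648, or 12.4%, at an unadjusted p under 0.05), and for day 7 against day 3 only 3 (2421, or 6.44%). None of these has a listed gene, and no named gene passed. The smallest p for day 7 against day 0 belonged to CYP83D1 (2.14), LOC100170751 (-1.81), LOC547835 (2.27), each with adjusted p = 0.0547, EN1 (-3.80, 0.0576) and GSTU30 (-2.25, 0.0611). For day 7 against day 3 they belonged to LOC547576 (-1.56, 0.12), EN1 (-3.34, 0.12), RCAALPHA (-1.70, 0.222), LOC100306092 (-1.52, 0.294) and SCOF-1 (-1.06, 0.294).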

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

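The tests of chance splits and of 35S day 0 replicate 1 alone were chosen before their results were seen, and the others reported here were chosen only afterwards.

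The results listed first are those in which the genotype difference itself changed between days by the test of that difference. From day 0 to day 3 it changed for 276 probe sets. Among named genes HSF-03 (3.49), HSP23.9 (3.46) and VSPA (3.32) moved toward 35S, and AOC4 (-2.66), GSTU30 (-2.41) and GDH1 (-1.98) toward Jack. At the probe sets named, the heat shock and vegetative storage genes were lower in 35S at day 0, and the jasmonate and glutathione transferase genes higher. Among lists, lipoxygenases moved toward 35S with a median of 1.49 (camera adjusted p = 0.0132; adjusted p = 0.447 with an estimated correlation), with LOX7 (2.64) and LOC547835 (1.78) passing and 4 genes adjusted over the list alone. Photosynthesis genes did so with a median of 0.826 (camera adjusted p = 0.000225; adjusted p = 0.323 with an estimated correlation), with ATPC (2.02), CHLH (2.01) and RCAALPHA (1.98) passing. WRKY factors moved toward Jack with a median of -0.378 (camera adjusted p = 0.000123; adjusted p = 0.447 with an estimated correlation), 0 of 53 passing and 6 adjusted over the list alone. NAC factors (-0.605, camera adjusted p = 0.0314; adjusted p = 0.741 with an estimated correlation) and defence genes (-0.781, camera adjusted p = 0.00577; adjusted p = 0.323 with an estimated correlation) did likewise. The day 0 arrays also enter the comparison at day 0, where each of these lists was called in the other direction. Between the genotypes at day 3 only photosynthesis among them was called. A loss of the day 0 differences can thus give these list changes, for photosynthesis in part. By fry the change from day 0 to day 3 was called for lipoxygenases, photosynthesis and defence, and for gibberellin genes by fry alone (adjusted p = 0.049). It was not called by fry for the WRKY (adjusted p = 0.165) and NAC (0.377) lists. The NAC call ended without Jack day 0 replicate 2 (-0.466), Jack day 3 replicate 1 (-0.296), 35S day 0 replicate 1 (-0.385) or 35S day 3 replicate 1 (-0.599). The lipoxygenase call ended without Jack day 3 replicate 2 (1.2) or 35S day 3 replicate 1 (1.38). The WRKY call stood with -0.665 without Jack day 3 replicate 2 and -0.624 without 35S day 0 replicate 2, and the defence call with -0.45 without 35S day 3 replicate 2.

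From day 0 to day 7 the genotype difference changed for 2 probe sets, and from day 3 to day 7 for 3, none with a listed gene. List medians from day 0 to day 7 moved toward Jack for WRKY factors (-0.573, camera adjusted p = 2.61e-06; adjusted p = 0.308 with an estimated correlation), NAC factors (-0.637, camera adjusted p = 0.000497; adjusted p = 0.495 with an estimated correlation) and glutathione transferases (-0.468, camera adjusted p = 0.000947; adjusted p = 0.423 with an estimated correlation). They did so for defence genes (-0.58, camera adjusted p = 0.000904; adjusted p = 0.24 with an estimated correlation), late embryogenesis abundant proteins (-0.395, camera adjusted p = 0.0324; adjusted p = 0.747 with an estimated correlation) and seed maturation genes (-0.517, camera adjusted p = 0.0307; adjusted p = 0.747 with an estimated correlation). They moved toward 35S for lipoxygenases (1.25, camera adjusted p = 0.00919; adjusted p = 0.308 with an estimated correlation), heat shock proteins (0.333, camera adjusted p = 0.0324; adjusted p = 0.308 with an estimated correlation) and photosynthesis genes (0.391, camera adjusted p = 0.000551; adjusted p = 0.24 with an estimated correlation). Of these 9 lists fry called only photosynthesis (adjusted p = 0.0284), and the others had adjusted p from 0.0548 to 0.67 by fry. The late embryogenesis call ended without either Jack day 0 array (-0.446 and -0.384), Jack day 7 replicate 1 (-0.41), 35S day 0 replicate 1 (-0.277) or 35S day 7 replicate 1 (0.0358). The seed maturation call ended without Jack day 0 replicate 1 (-0.587), Jack day 7 replicate 1 (-0.445), 35S day 0 replicate 1 (-0.293) or 35S day 7 replicate 1 (-0.0489). The heat shock call ended without Jack day 0 replicate 1 (0.137), Jack day 7 replicate 1 (0.405), 35S day 0 replicate 2 (0.159) or 35S day 7 replicate 1 (0.33), and the lipoxygenase call without 35S day 0 replicate 2 (1.39). Other calls stood without 35S day 0 replicate 1 with smaller medians, -0.191 for glutathione transferases, -0.334 for WRKY factors and -0.364 for NAC factors, and heat shock proteins with 0.718. With that array and Jack day 3 replicate 2 both left out the NAC (-0.364) and lipoxygenase (1.1) calls ended. The lipoxygenase median was 0.551 without Jack day 0 replicate 2 and 0.576 without 35S day 7 replicate 2, and that of heat shock proteins 0.598 without Jack day 0 replicate 2. The late embryogenesis and seed maturation medians were -0.669 and -0.82 without 35S day 0 replicate 2, and -0.941 and -1.17 without 35S day 7 replicate 2. From day 3 to day 7 gibberellin genes moved toward Jack with a median of -0.507, 17 of 22 negative (camera adjusted p = 0.00861; adjusted p = 0.221 with an estimated correlation). The count of 2 was 24 and 0 without Jack day 0 replicate 1 and replicate 2, 198 and 2911 without 35S day 0 replicate 1 and replicate 2, 0 without either day 3 array of either genotype, 0 and 4 without Jack day 7 replicate 1 and replicate 2, and 4 and 1 without 35S day 7 replicate 1 and replicate 2. The count of 3 was 10 without Jack day 7 replicate 1, 1 without 35S day 7 replicate 2, unmoved without either 35S day 0 array and 0 without any 1 of the others.

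Probe sets for Phytophthora sojae and Heterodera glycines, organisms the samples are not described as holding, also gave signal. On all 12 arrays 9 of them lay above 500, and 21 passed in at least 1 comparison of days. The highest intensity was 12340, while 18998 of the 23394 lay at or below background on all arrays. In the genotype comparisons 0 passed by limma, with 1471 at an unadjusted p under 0.05 at day 0, 1399 at day 3, 1123 at day 7 and 1375 averaged over the days. No explanation was tested for these signals.

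More probe sets differed between the genotypes at day 0, 1307, than at day 3 or day 7, although 35S day 0 replicate 1 lay apart from its replicate. This order rests on the fit to all arrays. With only the compared arrays fitted, fewer passed at day 0 than at day 3 or day 7, and 0 of the 20 named day 0 genes passed. Of the 500 probe sets furthest apart between the replicate 1 arrays, 90% had the same sign between the replicate 2 arrays, with a median difference of 1.18 against 4.01. This passed the bound of 75% set beforehand against that array as the whole source. Probe sets are not independent replicates, however, and those that change together can share a sign through the place of 1 array, so the test does not decide it. A genotype swap among day 0 arrays was argued against, since 16 of the 16 probe sets that passed at days 3 and 7 in one direction had both 35S day 0 arrays on the 35S side. Explants lying further along the response to culture could not be excluded, since 89% of the 500 probe sets furthest apart changed in the direction of culture in Jack, between the bounds of 90% and 75% that would have decided, so this and a genotype effect cannot be told apart. The genotype itself stays open and was not tested, as do differences in plant or embryo stage between harvests.

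The list of 25 storage protein and protease inhibitor genes was called toward 35S at day 3 with 0 genes passing and a median of 1.18 (camera adjusted p = 0.0233; adjusted p = 0.893 with an estimated correlation). The call ended without Jack day 3 replicate 2 (0.351) or 35S day 3 replicate 1 (1.02), and the median was 2.18 without Jack day 3 replicate 1. Replicates differed within groups, with a median difference between replicate 1 and replicate 2 of 1.97 in Jack at day 3, 0.929 in 35S at day 3 and -1.35 in 35S at day 7. With replicates this far apart in more than 1 group, a difference between single harvests and an effect of the genotype cannot be told apart, and both stay open.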

How the results depend on the processing

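Leaving out 35S day 0 replicate 1 and Jack day 3 replicate 2 together was chosen after the data were seen, and the other settings before. The 41 gene results named for the largest changes between the genotypes kept their call in 618 of 1001 combinations of result and setting. The 6 for a change of the genotype difference kept it in 56 of 143, and the 36 between days in 865 of 871. Further members of lists kept it in 700 of 1082, 134 of 297 and 14638 of 15661. No named gene that passed changed sign. For genes named for the largest changes at a single day or between days, the naming rule fixed this in advance when 1 array was left out. Called lists kept their call in 319 of 370 combinations, 329 of 372 and 1215 of 1317, and 4 of the others changed sign. Of results that did not pass, 5 of 29 for genes passed under some setting, and for lists 26 of 109 between the genotypes, 24 of 78 for the change and 34 of 133 between days. Where no reason is given below, the cause was not tested.

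Lists changed sign as follows. The phenylpropanoid median in Jack from day 0 to day 7 was -0.221 without _s_at and _x_at probe sets. In 35S versus Jack at day 0 it was -0.0371 without 35S day 0 replicate 1, the same with both arrays named above left out, and up to 0.626 over the other arrays left out in turn. The late embryogenesis median for the genotype difference at day 7 against day 0 was 0.0358 without 35S day 7 replicate 1 and as low as -0.941 over the others.

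Leaving out 1 array in turn, with the lone array assumed to vary like the other groups, gave counts from 78 to 6137 for the genotypes at day 0, 10 to 1336 at day 3, 16 to 68 at day 7 and 53 to 5334 averaged over days. The change of the genotype difference gave 0 to 3523 for day 3 against day 0, 0 to 2911 for day 7 against day 0 and 0 to 10 for day 7 against day 3. In Jack the ranges were 12239 to 17959 for day 3 against day 0, 13395 to 18860 for day 7 against day 0 and 1663 to 7737 for day 7 against day 3. In 35S they were 9403 to 14462, 11872 to 16169 and 1670 to 5459. Leaving out either array of a group takes the spread between them out of the fit, and the array that remains then stands for the group. With both arrays named above left out the genotype counts were 20 at day 3, 24 at day 7 and 260 averaged, those for the change of the difference were 125 for day 7 against day 0 and 1 for day 7 against day 3, and 6752 passed in 35S from day 3 to day 7.

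In the settings below, counts are for the genotypes at day 0, day 3, day 7 and averaged, then for the genotype difference at day 3 against day 0, day 7 against day 0 and day 7 against day 3, where they moved by more than 1.5 times. Adding 1 before the log2 gave 775, 82, 18, 240, 96, 1 and 0. Adding 64 gave 437 at day 3, 76 at day 7, 969 averaged, and 584, 158 and 1 for the changes. Median centring, quantile normalization and leaving out dim probe sets gave 19, 18 and 13 for day 7 against day 0. Leaving out _s_at and _x_at probe sets gave 5 for day 7 against day 3. With 1 probe set per gene, which tests fewer, the counts were 376, 100, 11, 118, 132 and 34, with 3255, 3389 and 1339 in Jack and 2847, 3195 and 972 in 35S for day 3 against 0, day 7 against 0 and day 7 against 3. Testing all probe sets of the table, which adjusts over more, gave 624, 79, 231 averaged, 39, 0 and 0. A variance trend with robust moderation gave 374 at day 3, 828 averaged, 479, 63 and 1.

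Array weights gave 188, 113, 175, then 0, 0 and 7, and 7516 in 35S from day 3 to day 7. The weights were 0.364 for the 35S day 0 arrays, 0.594 for Jack day 3 and 1.21 to 1.78 for the others, so both replicates of a group got the same weight. Fitting only the compared arrays, with fewer degrees of freedom, gave 0, 19 and 2 for the days (7813 at an unadjusted p under 0.05 at day 0 in the fit to all arrays), then 3, 0 and 0, with 3377 in Jack from day 3 to 7, and 8419 and 10466 in 35S from day 0 to 3 and 0 to 7. At adjusted p under 0.01 the counts were 96, 20, 21, 30, 0, 0 and 0, with 1982 and 1739 in Jack and 35S from day 3 to 7 and 8970 in 35S from day 0 to 3. Unadjusted p under 0.05 with at least 1.5-fold gave 5533, 3680, 1330, 2008, 5532, 4219 and 2118, and 6334 in 35S from day 3 to 7. Adjusted p under 0.05 with at least 2-fold gave 111 averaged, 10038, 11344 and 2943 in Jack, and 8425 and 10100 in 35S from day 0 to 3 and 0 to 7.

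A replicate block gave 92 at day 3, 134 for day 3 against day 0, 0 for day 7 against day 0 and 0 for day 7 against day 3. Deviations of arrays with the same number on the same day correlated across probe sets at 0.0701 at day 0, 0.0394 at day 3 and 0.0845 at day 7. Over the other pairs of groups the highest were 0.202 for Jack day 3 and 35S day 0 and 0.153 for Jack day 0 and Jack day 3, and the lowest -0.159 for Jack day 3 and 35S day 7. The block ended the calls of 6 of 11 named genes at day 3, GASA22 among them, of VSPA, AOC4 and GDH1 for day 3 against day 0, of DREB1 at day 0, LOC100306092 at day 7 and ERF5 averaged. It also ended the list calls of lipoxygenases at day 0 (-0.625) and photosynthesis at day 3 (0.345).

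Of the 20, 11, 2, 8 and 6 genes named at day 0, day 3, day 7, averaged and for day 3 against day 0, the numbers that passed were 20, 9, 2, 8 and 5 with median centring and 20, 9, 2, 8 and 3 with quantile normalization. They were 11, 4, 0, 3 and 1 with 1 added, 18, 10, 2, 8 and 6 with 64 added, 10, 4, 1, 3 and 1 with all probe sets tested, and 10, 5, 2, 7 and 0 with array weights. In the fit to the compared arrays, not run for the average, 0 of them passed by limma.

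Further list calls ended. With both arrays named above left out these were lipoxygenases at day 0 (-0.617) and for day 3 against day 0 (1.02), and in Jack storage proteins from day 0 to 3 (-2.55) and cell wall genes from day 0 to 7 (2.31). With all probe sets of a list's genes these were late embryogenesis at day 0 (0.353), and it (-0.301) and seed maturation (-0.343) for day 7 against day 0. Fitting only the compared arrays ended phenylpropanoids at day 0 (0.363) and heat shock proteins for day 7 against day 0 (0.333). Not all losses are named here, since that setting ended 6 list calls and array weights 2. In Jack, quantile normalization ended phenylpropanoids (0.926) and MYB (0.295) from day 0 to 3 and heat shock proteins (-1.91) from day 0 to 7. Median centring ended gibberellin genes (-1) from day 0 to 3. Adding 1 ended phenylpropanoids (0.948) and gibberellin genes (-1.08) from day 0 to 3 and NAC (0.688) from day 3 to 7. By fry 19, 24 and 14 lists were called in Jack for day 3 against 0, day 7 against 0 and day 7 against 3, and 24, 22 and 9 in 35S, among them every list called by camera.

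Of passing probe sets in Jack from day 3 to day 7, 61.5% rose, against 36.0% after median centring and 48.1% after quantile normalization. In 35S 51.8% rose from day 0 to 7, against 39.8% after median centring, and 61.4% from day 3 to 7, against 47.3%. Which direction prevailed between days thus depended on the scaling, while the direction of the named genes did not. Signal over background limits the 3444 soybean probe sets that lay at or below it on all arrays. Not run were the settings for GmAGL15, which has no listed probe set, the fit to compared arrays for the averaged contrast, which uses all arrays, and list values with 1 probe set per gene or all probe sets tested, which leave list values as they are.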

Other observations

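The test of chance splits was chosen before its result was seen, and the tests of a constant difference between the lines and of a sequence variant only afterwards.

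Of 22 gibberellin genes 13 fell and 3 rose in Jack from day 0 to day 3, with GASA3 at least 320-fold lower, GASA12 (-5.27) and GASA29 (4.84) (median -0.939, camera adjusted p = 0.0441; adjusted p = 0.321 with an estimated correlation). That call ended without Jack day 0 replicate 2 (-0.859) or either 35S day 7 array (-0.939) and without _s_at and _x_at probe sets (-0.797). GA20OX3, for a gibberellin synthesis enzyme, was at least 9.62-fold lower, and GA2OX8, for an inactivating enzyme, rose by 2.35. The auxin list was not called at day 7 (camera adjusted p = 0.957), with 3 of 8 rising, AUX22 (5.16), AUX28 at least 16.9-fold and the transport gene PIN2A (2.80), and 2 falling, one of them ADR11 (-4.22). In the brassinosteroid list CYP90A15 (3.61), BRI1B (1.70), BEHL1 (1.45) and BIN2 (0.47) rose by day 3 of 7 genes, and the list was not called (camera adjusted p = 0.0538). At day 0 the genotypes did not differ in these lists by camera (adjusted p = 0.973, 0.614 and 0.625), with 0 genes passing by limma in each.

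Cell wall genes rose in 8 of 12 and fell in 2 in Jack by day 7, with PRP2 (6.74), PRP3 (6.27) and CIM1 at least 35.3-fold higher (median 2.31, camera adjusted p = 0.0409; adjusted p = 0.293 with an estimated correlation), a call that ended without Jack day 0 replicate 2 (2.58) or either Jack day 3 array (2.31) and without _s_at and _x_at probe sets (2.31). Aquaporins fell in 10 of 21 and rose in 2 by day 3, with PIP2-8 (-6.48) and SIP1-6 at least 25.2-fold lower (camera adjusted p = 0.0522). Among 18 reactive oxygen genes 7 rose and 7 fell, with the alternative oxidase AOX1 at least 213-fold higher, PRX4 (6.36) and PRX2 (-5.88) (camera adjusted p = 0.971). Of 58 bZIP genes 14 rose and 19 fell, with BZIP42 (5.12) (camera adjusted p = 0.971). Sugar genes went both ways, with CIF1 (4.43) and STP1 (4.81) rising and the sucrose transporter SUT1 falling (-3.48) (camera adjusted p = 0.954). The leaf regulators LOC100500026 (-3.03), LOC100785458 (-1.66) and LOC100500091 (-1.13) fell. The reference genes TUBB3 (-2.25) and an actin, LOC100798052 (-1.94), fell in Jack by day 3, so they were not constant over culture. Genes of other tissues were tested as a check of dissection. Of 5 seed coat and pod genes SCB1 was lower in 35S at day 0 and 4 did not pass (camera adjusted p = 0.365), and of 8 sieve element genes 0 passed by limma (camera adjusted p = 0.828).

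Reporter and vector controls on the array, 35 probe sets, gave 0 calls by limma between genotypes averaged over days, with 1 at an unadjusted p under 0.05. Their highest intensity was 67.4, and 0 of them lay above background on all 35S arrays and on no Jack array.

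At all 3 days 14 probe sets differed between the genotypes in one direction. In the averaged comparison 1 of 100 drawn splits of the arrays within days (of 108 distinct ones), the real one, gave as many as its 543 probe sets. The highest of the others gave 99. The other splits put genotype differences into the spread within groups, which lowers their counts. Differences between plants or harvests of the lines were not addressed by the splits, and the 14 probe sets were not counted in them. Chance is thus not excluded for the 14. Of the 14, 13 had genotype differences that lay less than 1 apart on the log2 scale over the days, with a median spread of 0.407. The 14 were chosen for passing at all days, which favours differences that change little. The test of a change from day 0 to day 3 recovered 8% of simulated changes of 1, but in probe sets drawn at random and not in ones like the 14. A difference that does not depend on the day thus cannot be told apart from one that changes modestly with it. A sequence variant under the probes, with no change in transcript level, was also considered, and 4 of the 14 lay at or below background on all 6 arrays of the lower genotype. The values hold no single probes, so this cannot be told apart from a change in transcript level. The transgene, its place of insertion and background differences between the lines stay open and were not tested.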
